A study of Homo sapiens with 12 samples.

How the data were processed

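Total RNA of 2 established human neuroblastoma cell lines, SK-N-AS and SK-N-FI, was measured on Affymetrix 133plus2.0 arrays after transduction with an inducible lentiviral construct that expressed either an shRNA against FOXR2 or a scrambled shRNA. The groups and the replicate numbers were taken from the sample titles. Each line and shRNA had 3 arrays, 12 in all. The sequence of the shRNA, the inducer and the time of induction are not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

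The deposited values are signal intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5 and GCOS, without versions or settings. The values themselves show the scaling: without the lowest and highest 2%, the mean of every array was 100. They were not log transformed. Scanner files, detection calls and scan dates were not used here, so no scan batch was tested. MAS5 scales each array by 1 factor, which leaves differences in the shape of the signal distribution in place. The lower quartile of signal lay between 5.1 and 5.4 in the SK-N-AS arrays labelled FOXR2 shRNA and between 3.3 and 3.9 in the other arrays, and this difference reaches dim probe sets most. No array duplicated another. The number of arrays limits the precision.

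Of the 54675 probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several, 11721 carried none and 62 were control probe sets. Symbols were updated through the gene ID with the RefSeq gene table of GRCh38.p14, which was used for names and gene classes only, and 41043 of the probe sets with 1 gene matched. No gene was named from a probe set with several symbols, and no coordinates are given because the files name no genome build. The table held 19775 genes. Each gene was represented by its probe set with the highest mean log2 signal, and it was tested where that probe set's signal exceeded the median of its array in at least 3 of the 12 arrays. This left 13362 genes, 13346 of them matched to the current annotation. Of the 7013 genes with several probe sets past this filter, 382 had probe sets that changed in both directions in SK-N-AS and 39 in SK-N-FI.

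Signals were analysed as log2(signal + 4), the pseudocount being the median of the arrays' lower quartiles rounded to a whole number. Fold changes are on this scale, which understates the change of dim genes. One linear model of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with 8 residual degrees of freedom before moderation. The contrasts were FOXR2 shRNA minus scrambled shRNA in each line, the difference between those changes (SK-N-AS minus SK-N-FI), their average, and SK-N-AS minus SK-N-FI under scrambled shRNA. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. FOXR2, MYC and MYCN were taken from a fit without the filter on low signals and were also tested by a two-sided exact permutation test of 3 against 3 arrays, which cannot give a p below 0.1. The contrasts of both lines share no arrays, so their overlap was set against the product of the list sizes over the genes tested.

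A set of 28 gene lists was written before the data were examined, and each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast. The lists cover cell cycle, MYC targets, neuroblastoma identity, signalling, stress, metabolism and translation, with markers of Schwann, fibroblast, blood and endothelial cells for cell types that such cultures could hold. Camera with an estimated correlation and fry, which does not compare a list with other genes, were the alternatives.

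Genes named in the text followed a rule also fixed before the data were examined. For each line these are the 10 highest and 10 lowest fold changes among genes past the threshold whose 3 arrays all lay on one side of the other 3 and whose brighter group exceeded 14.7, the mean of the array medians. Added to them were the 10 risen and 10 fallen genes with the largest smaller change over both lines, the 5 highest and 5 lowest differences between lines, the 5 highest and 5 lowest genes between the lines under scrambled shRNA, members of the adrenergic and mesenchymal lists for that comparison, and up to 4 members of each list with the smallest adjusted p in a line. FOXR2, MYC and MYCN were named regardless, and genes with a LOC, orf or ENSG name were skipped. KIAA0754 was kept under its platform symbol, which was not matched to the current annotation.

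The fit was tested on simulated data for the 13362 genes. Of genes given a log2 change of 0.5, 1 and 2, it called 56.72%, 79.1% and 98.48% in the SK-N-AS comparison and 55.22%, 77.61% and 96.97% in the SK-N-FI comparison, and 0.07% of unchanged genes in either. The simulation changed only 67, 67 and 66 genes per line and used independent noise. Far more genes were called in the data, so these rates need not hold there. Alternatives were a pseudocount of 1 or 16, no filter or a filter at the 75th percentile, quantile normalization or median centring of the arrays, the mean of a gene's probe sets or each probe set on its own, array weights, eBayes without the trend or robust, each line fitted alone, the replicate number as a block, a minimum of 2-fold, and leaving out each array in turn. A fit of protein-coding genes only was added after the data were seen.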

Results

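Gene expression was profiled in SK-N-AS and SK-N-FI, 2 human neuroblastoma cell lines, each transduced with an inducible lentivirus expressing an shRNA against the forkhead transcription factor gene FOXR2 or a scrambled shRNA. Each of the 4 groups held 3 arrays, 12 in all. Signals were MAS5 intensities on a linear scale with a trimmed mean of 100 per array. Correlations of log2 signals over all probe sets lay between 0.97 and 0.981 within groups. They lay between 0.976 and 0.977 for FOXR2 against scrambled shRNA in SK-N-FI, between 0.943 and 0.949 in SK-N-AS, and between 0.883 and 0.916 across the lines. The SK-N-AS arrays labelled FOXR2 shRNA stood apart at the dim end, with median signals of 18.7 to 19 against 12.4 to 14.5 on the other arrays.

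The first comparison asks whether the targeted transcript was lower. In SK-N-FI, the FOXR2 signal fell from 179.4 ± 8.1 under scrambled shRNA to 99.47 ± 12.3 under FOXR2 shRNA (SD, n = 3 each). This was a log2 fold change of -0.83 (SE 0.0884, limma adjusted p = 1.35e-05), or -43.8%. In SK-N-AS it went the other way: the signal was 231.5 ± 13.2 in the arrays labelled FOXR2 shRNA and 184.2 ± 13.9 in the scrambled arrays (SD, n = 3 each). That was a log2 fold change of 0.32 (SE 0.0884, limma adjusted p = 0.00923). With each array centred on its median the SK-N-AS value was 0.23 and its limma adjusted p 0.0805, so that call depended on the scaling. In both lines the 3 values of one group lay on one side of the other 3 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The changes differed between the lines by 1.16 on the log2 scale (SE 0.125, limma adjusted p = 7.65e-06). Because the targeted gene goes against the label in SK-N-AS, the groups of that line are called the arrays labelled FOXR2 shRNA and the scrambled arrays throughout, and directions in SK-N-AS follow the labels, not a measured loss of FOXR2.

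MYC, the oncogenic transcription factor gene, rose in both lines. Its signal was 265.2 ± 8.02 against 148.9 ± 3.4 in SK-N-FI (SD, n = 3 each; log2 fold change 0.82, SE 0.0604, limma adjusted p = 3.9e-07). In SK-N-AS it was 628.5 ± 48.8 in the arrays labelled FOXR2 shRNA against 411.9 ± 14.5 (SD, n = 3 each; log2 fold change 0.60, SE 0.0604, limma adjusted p = 1e-06). The difference between these changes did not pass (limma adjusted p = 0.0963). MYCN, its neuronal paralog, was bright in SK-N-FI, at 844.2 ± 26.5 under FOXR2 shRNA and 845.3 ± 48.2 under scrambled shRNA (SD, n = 3 each; exact permutation p = 1). In SK-N-AS the MYCN signal was dim, 9.633 ± 7.45 against 5.767 ± 4.92 (SD, n = 3 each; exact permutation p = 0.6), with a log2 fold change of 0.43 (limma adjusted p = 0.408). Without replicate 3 of the SK-N-AS arrays labelled FOXR2 shRNA it was 0.92 (limma adjusted p = 0.0252). The arrays left in that fit still overlapped, with 17.1 and 9.6 against 4.5, 11.2 and 1.6. The pooled limma SE for MYCN, 0.354 in either line, includes the spread of these dim values. It also includes the tighter values of SK-N-FI, so the limma p-values do not measure the MYCN spread of SK-N-AS alone.

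**Figure D1:**
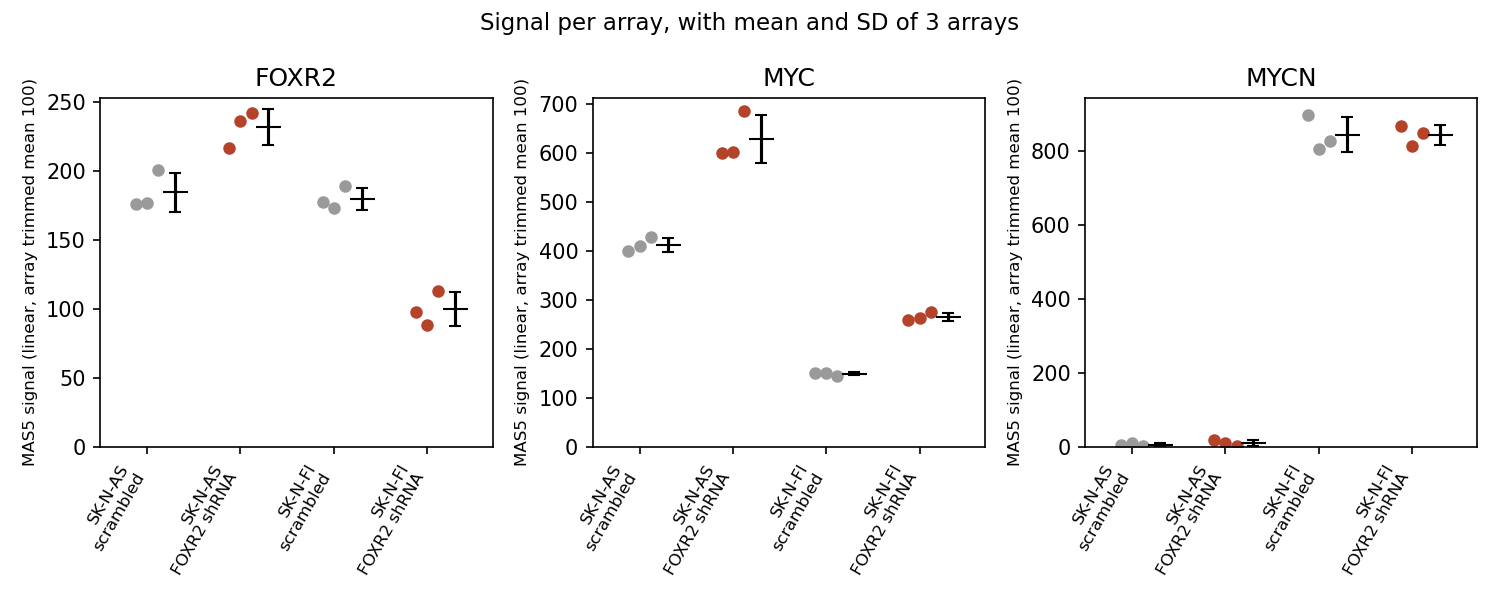
MAS5 signal (linear scale, trimmed mean of each array 100) of FOXR2, MYC and MYCN on each of the 12 arrays, in grey for scrambled and red for FOXR2 shRNA, with black bars for the mean and SD of 3 arrays. FOXR2 lies between 88.1 and 112.6 in SK-N-FI under FOXR2 shRNA and between 216.7 and 242 in the SK-N-AS arrays labelled FOXR2 shRNA, while the scrambled arrays of both lines lie between 172.9 and 200.2.

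In SK-N-AS, genes of DNA replication and mitosis were lower almost throughout in the arrays labelled FOXR2 shRNA. Of 34 tested genes of mitosis and G2/M, 33 fell and 1 did not pass, with a mean log2 fold change of -0.89. BIRC5, which encodes survivin, was at -1.5 (SE 0.0462), CCNB1 (cyclin B1) at -1.07 and AURKA (Aurora kinase A) at -1.15. Of 32 genes of DNA replication and G1/S, 31 fell, with a mean of -0.96. UHRF1 was at -1.27, the replicative helicase subunit gene MCM2 at -1.26 and the polymerase subunit gene POLE2 at -1.49. These counts were equal when adjusted over the list alone, 33 and 31. The SK-N-AS direction follows the labels, under which FOXR2 itself was higher.

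Lists of growth and metabolic genes were also lower in these SK-N-AS arrays, in which MYC was higher. Among MYC targets in metabolism and growth, 23 of 27 fell and none rose (24 adjusted over the list alone), with a mean of -0.61. Examples are EIF4EBP1 (a translation repressor), at -1.52, RCC1 at -1.38 and PAICS (purine synthesis) at -0.71. Among MYC targets in ribosome biogenesis, 23 of 27 fell (23 adjusted over the list alone, which also called 1 gene higher), including LYAR at -1.38 and NOP58 at -0.68. Of 41 mitochondrial translation genes, 31 fell (31 adjusted over the list alone), including MRPL1 at -0.85 and MRPL39 at -0.74. Of 31 hypoxia and glycolysis genes, 23 fell and 5 rose (23 and 5 adjusted over the list alone). PGAM1 (a glycolytic mutase) was at -1.66 and PDK1 at -1.90, whereas the glucose transporter gene SLC2A3 rose by 1.67.

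Signalling and stress lists moved too. Of 20 TNF and NF-kappaB response genes, 12 fell and none rose (13 adjusted over the list alone), with the adhesion gene VCAM1 at -2.10 and the chemokine genes CCL2 at -2.21 and CXCL8 at -2.26. Of 26 MAPK and ETS output genes, 15 fell and 7 rose (16 and 7 adjusted over the list alone), among them DUSP6, an ERK phosphatase, at -2.01 and EGR1 at -1.98. Of 32 ATF4 and amino acid response genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone), with PSAT1 (serine synthesis) at -2.02 and ATF4 itself at -0.83. Of 26 neuronal differentiation genes, 13 fell and 6 rose (13 and 7 adjusted over the list alone). NPY was at -2.35 and GAL at -2.42, both neuropeptide genes, while MAP2 rose by 1.74. Of 28 adrenergic identity genes, 13 fell and 4 rose (13 and 4 adjusted over the list alone). DDC (catecholamine synthesis) was at -1.32 and PHOX2A at -1.80, while STMN2 rose by 1.74. With an estimated correlation these last lists did not pass (adjusted p = 0.117 for neuronal differentiation and 0.16 for adrenergic identity), and the adrenergic list was also lost with the filter at the 75th percentile (adjusted p = 0.0777).

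Higher groups were fewer in SK-N-AS. Of 18 genes of MHC class I antigen presentation, 13 rose and none fell (14 adjusted over the list alone), with a mean of 0.53. HLA-B rose by 1.31 (SE 0.0768), HLA-C by 1.18, HLA-E by 1.04 and HLA-F by 1.05, and probe sets of these near-identical genes can cross-hybridise. Of 25 genes of cholesterol and fatty acid synthesis, 13 rose and 2 fell (13 and 2 adjusted over the list alone). STARD4 rose by 0.64 and LSS by 0.75, whereas INSIG1, a brake on sterol synthesis, fell by 0.52. This list lost its call with the mean of a gene's probe sets (mean 0.23, camera adjusted p = 0.113).

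Over all genes, 6646 of 13362 changed in SK-N-AS, 3316 higher and 3330 lower in the arrays labelled FOXR2 shRNA, and 534 and 487 of these by at least 2-fold. The share of higher calls, 49.9%, was 44.2% with quantile normalization and 44% with each array centred on its median. Groups did not overlap for 7728 genes (57.8%), against 10% by chance. The largest rises were LGI1, a secreted synaptic protein gene, with 233.9 ± 33.1 against 8.5 ± 3.2 (SD, n = 3 each; log2 fold change 4.28, limma adjusted p = 1.249e-10), and IGFBP3, an insulin-like growth factor binding protein gene, with 1389 ± 109 against 92.7 ± 3.58 (SD, n = 3 each; 3.85, limma adjusted p = 1.324e-11). The RNA genes FTX, ASAP1-IT1, SPRY4-IT1 and KCNQ1OT1 rose by log2 fold changes between 2.76 and 3.24, with KIAA0754 at 3.11, RPS16P5 at 2.96, PSG1 at 2.77 and ANKRD36B at 2.71. The largest fall on the log2(signal + 4) scale was GCG, the preproglucagon gene, from 2556 ± 60.3 to 270.9 ± 22.7 (SD, n = 3 each; -3.22, limma adjusted p = 5.638e-13). The pseudocount affects this ranking and that of the rises: CPXM1, from 39.8 to 2.43, fell more as a ratio of signals. VGF, a neuropeptide precursor gene, was at -2.80 and the cell cycle phosphatase gene CDC25A at -2.78. CPXM1, SLC39A8 (a metal ion transporter gene), CYTL1, FKBP1B, CRIP1, UTS2 (urotensin 2) and KHK (ketohexokinase) lay between -2.76 and -2.51.

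Camera passed 13 of the 28 lists in SK-N-AS, 2 higher and 11 lower, and 11 of them held with an estimated correlation. Camera adjusted p at the preset correlation was 1.26e-18 for mitosis, 2.29e-18 for DNA replication and 4.35e-05 for MHC class I. With an estimated correlation it was far larger, at 0.00701, 0.000209 and 0.01. The rest did not pass. Risen and fallen members were 4 and 5 of 11 histone genes, 6 and 8 of 21 p53 targets, 5 and 6 of 19 apoptosis regulators, 5 and 10 of 26 mesenchymal identity genes, and 16 and 7 of 32 matrix and TGF-beta genes. They were 4 and 8 of 28 interferon response genes, 9 and 6 of 26 unfolded protein response genes, 4 and 6 of 19 heat shock genes, 4 and 10 of 40 oxidative phosphorylation genes, 0 and 2 of 40 ribosomal protein genes, 6 and 4 of 15 FOX genes, and 7 and 7 of 23 MYC network members. Lists of other cell types' markers did not pass: 1 and 2 of 8 Schwann, 4 and 3 of 13 fibroblast and 0 and 1 of 5 blood and endothelial markers rose and fell. The arrays labelled FOXR2 shRNA also had a lower quartile of 5.1 to 5.4 against 3.5 to 3.9 in their scrambled controls. Calls of RNA genes (203 higher, 59 lower of 801) and pseudogenes (80 higher, 15 lower of 218) were mostly higher, unlike those of protein-coding genes (3028 higher, 3255 lower of 12327). Most members of the first 2 classes did not pass. RNA genes were called higher about as often as protein-coding genes (25.3% against 24.6%), and the contrast lay in fewer lower calls (7.37% against 26.4%).

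In SK-N-FI, where FOXR2 was reduced, ACTA2 and IGFBP7 led the rises and SST and GCG the falls. ACTA2, smooth muscle actin, rose from 181.5 ± 11.5 to 1114 ± 58.8 (SD, n = 3 each; log2 fold change 2.59, SE 0.0893, limma adjusted p = 1.759e-11). The actin-binding protein gene TAGLN rose by 2.03 and IGFBP7 by 2.39. NGFR, a neurotrophin receptor gene, rose by 1.63, DCN (decorin) by 1.58 and the connexin gene GJA1 by 1.55, with MMP15 at 2.22. Some of these also rose past the threshold in SK-N-AS: ACTA2 by 0.95, TAGLN by 0.94, NGFR by 0.96 and DCN by 0.25. There GJA1 was at -1.56, and IGFBP7 and MMP15 did not pass. NGFR (1.13 to 6) and TAGLN (13.3 to 28.1) were dim in SK-N-AS, where the arrays labelled FOXR2 shRNA read higher at the dim end. The other tested TAGLN probe sets gave 0.62 and 0.00422 in SK-N-AS, and 2.34 and -0.232 in SK-N-FI. SST, somatostatin, fell from 742.8 ± 53.2 to 138.2 ± 0.907 (SD, n = 3 each; -2.39, limma adjusted p = 2.538e-06), while in SK-N-AS, where it was dim, it rose by 0.88 (limma adjusted p = 0.005275).

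GCG was dim in SK-N-FI and went from 18.8 ± 0.608 to 0.667 ± 0.153 (SD, n = 3 each; -2.29, limma adjusted p = 1.03e-10), and UTS2 was at -2.10. MAP1LC3C, an autophagy gene of the LC3 family, was at -2.26, the kinase gene NEK7 at -1.95, the proton pump subunit gene ATP6V1D at -1.47 and STC1 at -1.51. HTATSF1P2, TAFA2 and RRAGD lay between -1.57 and -1.54. HMGA2 was at 1.74 by its brightest probe set but at 0.13 by the mean of its probe sets (limma adjusted p = 0.669). KCNC1 (1.57) and ACTA2-AS1 (1.5) no longer passed without SK-N-FI scrambled replicate 1 (log2 1.09 and 1.30, limma adjusted p = 0.0654 and 0.0569).

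Among the fixed lists, 12 of 32 ATF4 and amino acid response genes fell and none rose in SK-N-FI (13 adjusted over the list alone). PSAT1 was at -0.48 and PSPH at -0.47, both of serine synthesis, with VEGFA at -0.45 and GDF15 at -1.26. Of 27 MYC targets in ribosome biogenesis, 8 fell and 2 rose (9 and 2 adjusted over the list alone), with LYAR at -0.72 and WDR43 at -0.84. Of 25 cholesterol and fatty acid synthesis genes, 9 rose and 2 fell (13 and 2 adjusted over the list alone), with SQLE at 0.42 and LSS at 0.49. Of 32 matrix and TGF-beta response genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with CCN1 at 0.83, COL5A1 at 0.77 and LUM at 0.53. Few mitosis genes changed: 1 rose (CCNA2, 0.39) and 2 fell (BIRC5, -0.51, and KIF20A, -0.29) of 34 (1 and 2 adjusted over the list alone). Of 32 DNA replication genes, 1 rose and 3 fell (1 and 2 adjusted over the list alone), and the call of RFC4 was lost with the replicate block. Of the other cell type markers, 2 of 8 Schwann and 3 of 13 fibroblast markers rose (PDGFRA not with the replicate block) and 1 fibroblast marker fell, with no call among 5 blood and endothelial markers, and none of these lists passed.

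In total 3009 of 13362 genes changed in SK-N-FI, 1680 higher and 1329 lower, and 51 and 70 of these by at least 2-fold. The share of higher calls, 55.8%, was 48.6% with each array centred on its median, so which direction held more calls depended on the scaling. Groups did not overlap for 5084 genes (38%), against 10% by chance. Camera passed 4 lists, ATF4 (adjusted p = 7e-05), MYC ribosome biogenesis (0.00823), cholesterol (0.0171) and matrix (0.0313). With an estimated correlation none passed (adjusted p = 0.0597, 0.107, 0.107 and 0.335). With the mean of a gene's probe sets the cholesterol list was lost, its mean going from 0.133 to 0.0525 (adjusted p = 0.284), and so was the matrix list, from 0.237 to 0.143 (0.0764). The matrix list also missed the threshold with a pseudocount of 1 (0.0534) and with the filter at the 75th percentile (0.11). The number of lists was 12 without the filter on low signals, and it depended on single arrays: it was 10, 8 and 7 without SK-N-FI scrambled replicate 1, scrambled replicate 3 and FOXR2 replicate 3, and the matrix list was lost without FOXR2 replicate 2 (adjusted p = 0.0677).

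**Figure D2:**
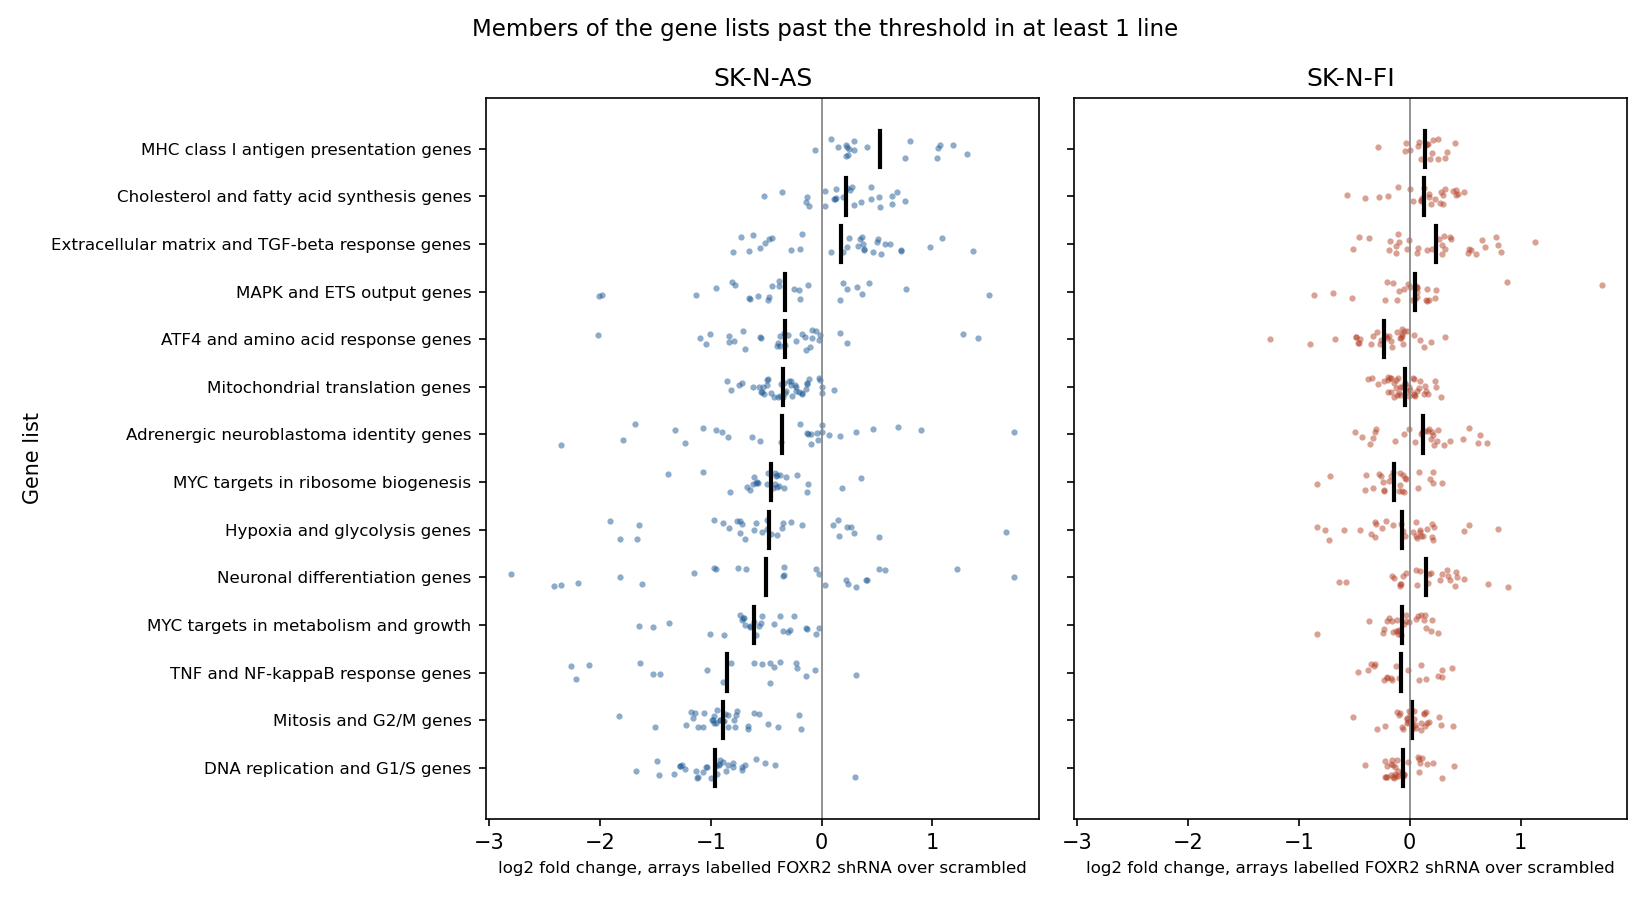
Log2 fold change of each tested member (points) and the list mean (black bar) in SK-N-AS (blue) and SK-N-FI (red), for the gene lists that passed camera in at least 1 line, with vertical jitter for visibility. Mitosis genes average -0.886 in SK-N-AS and 0.0211 in SK-N-FI, and MHC class I genes 0.529 and 0.141.

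The lines shared more changes than independent lists would. GCG, UTS2, ATP6V1D, SLC39A8, MAP1LC3C and STC1 fell in both, as did the sugar transporter gene SLC35B4 (-1.88 in SK-N-AS and -1.22 in SK-N-FI), HS6ST2 (-1.22 and -1.21), the chromatin remodelling subunit gene SMARCD2 (-1.26 and -1.18) and MAT2B (-1.17 and -1.18). TMTC4 rose by 1.16 and 1.21, TP53INP1, a p53-responsive gene, by 2.26 and 1.13, EBLN2 by 1.48 and 1.33, LINC02593 by 1.95 and 1.32, FAM228B by 1.21 and 1.09, SLC46A3 by 1.13 and 1.08, and WWC3 by 0.99 and 1.18. In SK-N-AS these directions follow the labels. The rule for shared genes set no minimum signal beyond the filter, and some were dim. In SK-N-FI EBLN2 went from 2.8 to 12.9 and LINC02593 from 5.47 to 18.5, so background and the pseudocount affect their values. The SK-N-FI calls of TP53INP1 and SLC39A8 were lost with the mean of a gene's probe sets (0.32 and -0.41, limma adjusted p = 0.215 and 0.146).

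Together 908 genes were higher in both lines, against 416.9 for independent lists, and 813 were lower in both, against 331.2. Opposite calls numbered 148 (higher in SK-N-AS, lower in SK-N-FI) and 257 (lower in SK-N-AS, higher in SK-N-FI), against 329.8 and 418.7. Both lines share 1 estimate of each gene's spread, so a gene with a small spread tends to be called in both. The counts for independent lists may therefore be too low in every direction, but opposite calls were still fewer than these counts. At 2-fold or more, 8 genes were higher in both and 25 lower in both, against 2.038 and 2.551. Across genes, which are not independent replicates, the changes correlated with r = 0.286 and rho = 0.3. The average change over both lines passed for 6264 genes, 3210 higher and 3054 lower (51.2% higher, and 44.6% with each array centred on its median). The shared risers CUBN (1.05 and 1.15), LRRN2 (1.08 and 1.02) and DNAI4 (2.17 and 1.00) each lost a call when an array was left out. Without SK-N-FI scrambled replicate 3 the SK-N-FI values were 0.68 for CUBN and 0.72 for DNAI4 (limma adjusted p = 0.104 and 0.092), and without SK-N-FI scrambled replicate 1 that of LRRN2 was 0.65 (limma adjusted p = 0.186). CUBN also lost its SK-N-AS call with quantile normalization (0.70, limma adjusted p = 0.103). LRRN2 lost its SK-N-FI call with the mean of probe sets (0.47, limma adjusted p = 0.118), and also without the filter, without the trend and with each line fitted alone (limma adjusted p = 0.0723, 0.102 and 0.0871).

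**Figure D3:**
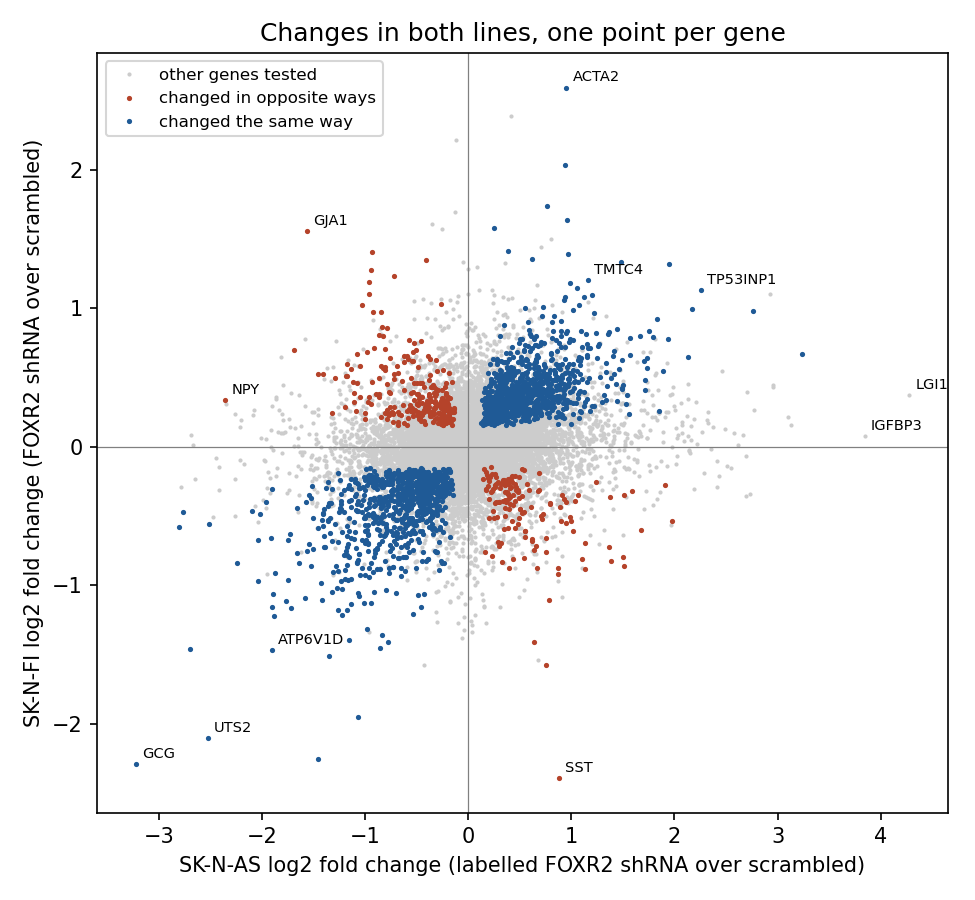
Log2 fold change of each tested gene in SK-N-AS (x axis, arrays labelled FOXR2 shRNA over scrambled) against SK-N-FI (y axis), with genes past the threshold in both lines in blue (1721, same direction) or red (405, opposite directions) and other genes in grey. GCG and UTS2 lie at the lower left, SST at the bottom and ACTA2 at the top.

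The response differed between the lines for 4442 of 13362 genes, 1942 with the higher change in SK-N-AS and 2500 with the lower. LGI1 (difference 3.91), IGFBP3 (3.77), SST (3.27), SLC6A16 (3.05) and KIAA0754 (2.89) headed the first group. GJA1 (-3.11), CYTL1 (-2.78), NPY (-2.69), FKBP1B (-2.68) and TH, tyrosine hydroxylase (-2.66), headed the second. The mitosis list differed by a mean of -0.91 (camera adjusted p = 1.31e-22) and DNA replication by -0.90 (1.88e-20), and both held with an estimated correlation (adjusted p = 0.00446 and 0.000138). In all 12 lists differed and 9 of them held with an estimated correlation, while the ATF4 list did not differ at the threshold (camera adjusted p = 0.139). These differences include that FOXR2 itself moved in opposite directions.

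Under scrambled shRNA alone, SK-N-AS had less of the neuronal and adrenergic transcripts and more of the fibroblast and interferon ones than SK-N-FI. Of 26 neuronal differentiation genes 22 were lower in SK-N-AS and 3 higher (22 and 3 adjusted over the list alone), and of 28 adrenergic identity genes 21 were lower and 5 higher (21 and 5 adjusted over the list alone), with CHGB at -5.28 and STMN2 at -3.51. Of 28 interferon response genes 24 were higher and 2 lower (24 and 2 adjusted over the list alone). Of 18 MHC class I genes 14 were higher and 3 lower (14 and 3 adjusted over the list alone), and of 13 fibroblast markers 9 and 1 (9 and 1 adjusted over the list alone), among them LUM at 4.34 and DCN at 4.44. Mesenchymal identity genes were split, 12 higher and 10 lower of 26 (12 and 10 adjusted over the list alone), with PRRX1 at 5.90 and MAFF at -2.21. The widest single differences were TYRP1 (8.13), GCG (6.81), EDIL3 (6.63), CFI (6.58) and S100A4 (6.57), higher in SK-N-AS, and QPCT (-8.30), GREM1 (-7.32), DLK1 (-7.23), POU3F3 (-7.14) and EDN3 (-6.95), lower in it. Most of these were dim in 1 of the lines, where the pseudocount of 4 holds the difference down, so their sizes and order depend on it. FOXR2 did not differ at the threshold (0.04, limma adjusted p = 0.791), MYC was higher (1.44) and MYCN lower (-6.56). In all 9469 genes differed, 5261 higher and 4208 lower, with a median over all genes of 0.107 that centring the arrays brought to -0.00929, and the share of higher calls from 55.6% to 48.3%. Camera passed 8 lists, 6 of them also with an estimated correlation. At the preset correlation adjusted p was 1.32e-07 for neuronal differentiation, 3.45e-06 for adrenergic identity, 0.000115 for interferon response, 0.00251 for MHC class I and 0.00111 for fibroblast markers. With an estimated correlation these were 0.0256, 0.0277, 0.0256, 0.0305 and 0.0305.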

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

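The tests of exchanged labels, of RNA degradation, of the shRNA acting on other transcripts and of the background for probe sets without a gene were chosen only after the results they concern were seen. The change from scrambled arrays to arrays labelled FOXR2 shRNA differed between the lines for 4442 genes by the test of the difference itself. In 100 of the 200 regroupings of shRNA within the lines, the real one included, 2 gave as many genes. The other, with 6264, was the real grouping with the labels of 1 line exchanged, which turns the difference into the average. The average itself (6264) was reached by 1 of the 100 regroupings, with 4442 as the highest other, and the 1721 genes changed the same way by 1, with 405 as the highest other. Random allotment of these arrays to the groups would seldom give these 3 counts. The ranks show only that the arrays of each line part along the labels. Any cause that parts them so, such as a batch, would give the same ranks. Chance differences between cultures are not excluded, since the labels do not say that the replicates were separate cultures. Regroupings that kept neither line's split gave 0 genes at most for each. For SK-N-AS (6646, highest other 0), SK-N-FI (3009, highest other 2) and the lines under scrambled shRNA (9469, highest other 0), the real split was 1 of 10, too few splits for a share under 0.05.

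FOXR2 was higher in the SK-N-AS arrays labelled FOXR2 shRNA, and its change exceeded that in SK-N-FI by 1.16 on the log2 scale. Exchanged labels of the SK-N-AS groups would turn the shared response around. However, the 70 genes at least 2-fold lower in SK-N-FI had a median of -0.512 in SK-N-AS (95% bootstrap interval over genes -0.949 to -0.258). This argues against exchanged labels for these genes and arrays, as far as the lines respond alike. The bootstrap intervals here and below resample genes or probe sets, which are not independent replicates. They leave out the spread between arrays. The 51 genes at least 2-fold higher in SK-N-FI decide less, with a median of 0.358 (interval -0.00518 to 0.71). The 2537 genes within 1.5-fold of the FOXR2 signal had a median change of -0.00573 (interval -0.0285 to 0.0183). This met the bound set beforehand for excluding a rise of probe sets as bright as FOXR2, but that bound was wrong because it left out their spread: they went both ways with an SD of 0.53, and the FOXR2 change stood at their 76.6th percentile. This reading was chosen after the value was seen. The same FOXR2 probe set changed by -43.8% in SK-N-FI, from a similar scrambled signal (179.4 against 184.2 in SK-N-AS). This argues against a probe set that misses the action of the shRNA, as far as both lines make the same transcript. What stays open is such a rise among other changes of that size, a construct other than the label says, or a true rise of FOXR2 in this line. Neither the construct nor a true rise could be tested, because the shRNA sequence and probe positions were not used here.

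Calls of probe sets without a gene were mostly higher in the SK-N-AS arrays labelled FOXR2 shRNA: 1934 of 4154 tested, outside all comparisons of the report, were higher and 392 lower, against 133 and 134 in SK-N-FI. In these arrays RNA genes were called higher about as often as protein-coding genes (25.3% against 24.6%) but lower less often (7.37% against 26.4%). Their median log2 fold change was 0.184 against 0.00222. RNA genes were dimmer, with a median scrambled signal of 20.7 against 149, which leaves less room for a fall. A background that lifts dim probe sets alike is argued against for probe sets without a gene, as far as these arrays go. They exceeded protein-coding genes of the same level by 0.38 (bootstrap interval over probe sets 0.345 to 0.412). For RNA genes the excess was 0.133 (bootstrap interval over genes 0.074 to 0.175) and 0.0766 after quantile normalization, which does not decide. Neither interval holds the spread between arrays. RNA degradation stays open: the 3' over 5' log2 ratio of control probe sets was higher in these arrays by 0.0838 for GAPDH (95% t interval -0.131 to 0.299), carried mostly by replicate 3, and by 0.00619 for ACTB (interval -0.0821 to 0.0944). The ACTB interval lies below a cutoff of 0.2, written after the results were seen, but the GAPDH interval does not. More intron-containing RNA or genomic DNA may be a source and stays open. Within genes, dimmer probe sets did not rise over the brightest (-0.0174, bootstrap interval -0.025 to -0.00829). This value met the bound set beforehand for excluding such a source, but that bound was wrong. Without probe positions the dimmer probe sets cannot be taken as intronic, and the probe sets without a gene were not in that test. This reading was chosen after the value was seen, and a biological change of RNA genes was not tested.

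More genes were at least 2-fold lower in both lines (25) than at least 2-fold higher in both (8). One shRNA acting on transcripts other than FOXR2 could give such an excess of shared falls, also in a line whose FOXR2 signal did not fall. A shared response to the scrambled shRNA in the controls would give it too, as would one to the targeted gene if FOXR2 were reduced in SK-N-AS against its measured signal, so these cannot be told apart here without the shRNA sequence.

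The following named genes differed between the lines by the interaction test, given as the SK-N-AS minus the SK-N-FI log2 change. Positive were LGI1 (3.91), IGFBP3 (3.77), SST (3.27), SLC6A16 (3.05), KIAA0754 (2.89), FTX (2.57), RPS16P5 (2.53), PSG1 (2.51), ASAP1-IT1 (2.51), TAFA2 (2.33), ANKRD36B (2.31), RRAGD (2.22), KCNQ1OT1 (1.78), DNAI4 (1.18), HTATSF1P2 (1.15), TP53INP1 (1.13) and NEK7 (0.88). Negative were GJA1 (-3.11), CYTL1 (-2.78), NPY (-2.69), FKBP1B (-2.68), TH (-2.66), CDC25A (-2.49), CRIP1 (-2.42), MMP15 (-2.33), CPXM1 (-2.29), VGF (-2.22), IGFBP7 (-1.98), KHK (-1.95), KCNC1 (-1.83), ACTA2 (-1.64), DCN (-1.33), SLC39A8 (-1.24), HMGA2 (-0.97), GCG (-0.93), SLC35B4 (-0.66) and ATP6V1D (-0.44). A negative value need not mean a fall in SK-N-AS: ACTA2 and DCN rose in both lines, by less in SK-N-AS. The value of GCG does not show the larger fall in SK-N-AS: its SK-N-FI signal ended near 0, where the pseudocount of 4 caps the fall, and with a pseudocount of 1 the difference was 0.338 (adjusted p = 0.133). HMGA2 and ATP6V1D also turned, to 0.105 and 0.243, with the mean of a gene's probe sets. KCNQ1OT1, KCNC1, DNAI4 and TP53INP1 lost the call under at least 1 alternative, such as a pseudocount of 1 for the first 3 (adjusted p = 0.11, 0.0938 and 0.0691) and the mean of probe sets for TP53INP1 (0.155).

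Among lists, the mean change differed by -0.907 for mitosis, -0.902 for DNA replication, -0.784 for TNF and NF-kappaB response, -0.653 for neuronal differentiation, -0.543 for MYC targets in metabolism, -0.477 for adrenergic identity, -0.41 for hypoxia and glycolysis, -0.372 for MAPK and ETS output, -0.315 for MYC targets in ribosome biogenesis, -0.3 for mitochondrial translation, -0.157 for oxidative phosphorylation and 0.388 for MHC class I. With an estimated correlation the adrenergic, oxidative phosphorylation and mitochondrial translation lists did not pass (adjusted p = 0.0858, 0.587 and 0.0807). The oxidative phosphorylation list was also lost under other alternatives, with a mean of -0.033 after quantile normalization (adjusted p = 0.862).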

How the results depend on the processing

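The fit of protein-coding genes only was added after the data were seen. Over 96 single-gene results, 2399 of 2428 values under the alternatives kept direction and side of the threshold, 26 lost the call, 1 gained it and 2 reversed, and over 17 list results 446 of 459 kept both and 13 lost the call. Of the flagged differences between lines, 845 of 865 values of 37 genes kept both, 17 lost the call and 3 reversed, and 284 of 288 values of 12 lists kept both. Nearly all of these genes, lists and differences were chosen because they passed in these same data. Leaving out an array of one line also leaves the fold changes of the other line as they were. High shares were therefore likely beforehand and do not measure how far the results would hold in new samples. FOXR2 in SK-N-AS was 0.23 (adjusted p = 0.0805) with median centring; the cause was not tested. The lists passing in SK-N-FI were 12 without a filter, 0 with an estimated correlation and 15 by fry, and in SK-N-AS 23 by fry, which asks another question; the cause of the first was not tested. Requiring 2-fold left 1021 genes in SK-N-AS and 121 in SK-N-FI by construction. Leaving out 1 array at a time gave 6019 to 6861 genes in SK-N-AS, 2302 to 3037 in SK-N-FI, 3913 to 4339 for the difference, 5881 to 6222 for the average, 9060 to 9486 between the lines, 1398 to 1683 for the same way in both, 13 to 14 lists in SK-N-AS and 3 to 10 in SK-N-FI. FOXR2 ranged from 0.29 to 0.38 in SK-N-AS and from -0.92 to -0.75 in SK-N-FI, and MYCN in SK-N-FI from -0.033 to 0.044, turning positive without scrambled replicate 1 (0.044) and without FOXR2 replicate 2 (0.024), a value near 0 whose sign carries no call. Dim genes, near the lower quartile of signal, are limited by signal over background and by the pseudocount.

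Samples with equal replicate numbers showed no shared deviation from the group means: their deviations correlated between -0.0286 and 0.0189, and those of unequal numbers between -0.0247 and 0.0413. This does not show whether equal numbers mark a shared culture or day. With the replicate block the counts were 6544 in SK-N-AS, 2826 in SK-N-FI, 4248 for the difference, 6135 for the average, 8070 between the lines and 1643 for the same way in both, with 13 lists in SK-N-AS, and all of the 96 single-gene and 17 list results stayed the same. The 12 list calls for the difference and the 8 between the lines were kept too, as were the calls of 105 list members in SK-N-AS and of 94 of 97 in SK-N-FI (lost were RFC4, IFIT1 and PDGFRA, the first and last of them counted among the changed SK-N-FI members in the report).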

Other observations

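Some p53-responsive genes changed the same way in both lines, while their list did not pass in either. TP53I3 rose by 0.97 in SK-N-AS (SE 0.0537) and 1.39 in SK-N-FI, CDKN1A by 0.52 and 0.38, while CCNG1 was at -0.48 and -0.32, each past the threshold. PMAIP1, an apoptosis gene of the BCL2 family, was at -1.41 and -0.48. These genes were chosen after their values were seen. In SK-N-AS, CD44, an adhesion receptor gene of the mesenchymal list, was at -1.89 while RUNX2 rose by 0.90, and in SK-N-FI RUNX2 was at -0.44.

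A pair of hypotheses arose from the named genes, and each was tested on a list written after those genes were seen and without them. The fall of GCG and UTS2 in both lines, VGF in SK-N-AS and SST in SK-N-FI may belong to a wider fall of peptide hormone and neuropeptide genes. However, SST was higher in SK-N-AS (0.88), where it was dim (4.53 to 10.7). The 27 tested other members had a mean log2 change of 0.0569 in SK-N-AS (95% bootstrap interval -0.169 to 0.29), with 5 higher and 4 lower. In SK-N-FI it was -0.0252 (interval -0.191 to 0.153), with 4 higher and 6 lower. The intervals in this paragraph resample genes and leave out the spread between arrays. Camera p was 0.872 and 0.842, so the test found no shift, while the intervals leave a fall of 0.1 open in either line. The rise of ACTA2 and TAGLN in SK-N-FI may belong to a rise of smooth muscle contractile genes. Both were also higher in SK-N-AS (0.95 and 0.94), where TAGLN was dim (13.3 to 28.1). The 23 tested other members had a mean of 0.127 in SK-N-FI (interval 0.0331 to 0.219), with 7 higher and 1 lower, but camera p was 0.0892 and 0.218 with an estimated correlation. In SK-N-AS the mean was -0.0967 (interval -0.314 to 0.108), with 8 higher and 4 lower, and camera p there was 0.895. Neither hypothesis passed its test, and these p-values were not adjusted. Some members, such as CHGA and SCG2, also stand in lists of the report, whose values had been seen.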
